A study of Mus musculus with 2 samples.

How the data were processed

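Arid1b ChIP-seq was compared with input in primary mouse dental mesenchyme cells, 1 library each. Chromatin was prepared with an enzymatic immunoprecipitation kit and Arid1b was precipitated with an antibody from Cell Signaling, per the labels. FastQC 0.11.8, Bowtie2 2.2.5, Picard and MACS2 2.1.1 and the build mm10 are named in the submitters' processing notes, without roles, order or parameters. Read numbers, filters and the handling of duplicates are not given in the sources used here. The name of the deposited list pairs the ChIP with the input, so no replicates were pooled.

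The deposited values are those of a narrow peak list without a header. For each peak the authors' list gives the position, a fold enrichment over input at the summit (a linear ratio), a -log10 p-value, a -log10 q-value, a score and the offset of the summit from the peak start. The deposited score equals 10 times the -log10 p-value without its decimals in 100% of peaks, so it was not used further. The lowest -log10 p-value in the list was 5.02. All fold, p and q values of peaks are the authors' and were used only to describe and filter peaks within the list. No interval was listed more than once.

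The summit pileup and the expected input level behind each peak were recovered from the authors' fold and p-value. This assumed that MACS2 gives the fold as pileup plus 1 over expected level plus 1 and the p-value as the Poisson probability of more than the observed pileup. Whole pileups solved both formulas within 0.001 in -log10 p in 100% of peaks, with a largest error of 0.000162. The exact Poisson 95% interval of the pileup, with the expected level held fixed, gave the interval of each fold. It covers counting error of the ChIP pileup only. The expected level was the genome background of 8.68 in 47.2% of peaks and a higher local input level in 4395 peaks. Total read numbers of the libraries were not used here.

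Genes came from an NCBI RefSeq table of GRCm38.p6, the assembly that mm10 names. It gives gene start and end without strand, exons or sequence. Promoters had been planned as 1 kb around start sites, with random lists matched on promoter GC content. In their place, peaks were assigned to either annotated boundary of a gene within 1 kb, and the random lists without GC matching, planned as an alternative, became the main test. Exon and intron classes became inside or outside a gene. Motif counts, a filter on repeats and GC-matched placements were not run, because no genome sequence was used here. Coordinates are 1-based.

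Summits were placed in 3 classes and compared with 1000 random placements of as many positions on each chromosome's annotated span. Shares have exact binomial (Clopper-Pearson) 95% intervals. The difference of median fold between boundary peaks and others has a bootstrap interval over peaks from 2000 draws. For each of 27 gene lists, the number of members with any part of a peak within 1 kb of a boundary was set against 10000 random lists of the same size from all 21887 protein-coding genes. The smaller tail share was doubled, adjusted by Benjamini-Hochberg over the 27 lists and called below 0.05. H19 and Meg3 are not protein-coding, so 20 of the 22 members of the Plagl1 and imprinted list were tested. The fold given for a boundary peak of a list member is that at its summit, which can lie more than 1 kb from the boundary.

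The lists, the alternatives and the rule for named genes were fixed before the data were examined. The lists were Hedgehog signalling, Plagl1 and imprinted growth genes, SWI/SNF subunits, S and G2/M phase, cell cycle arrest, dental mesenchyme, odontoblast and mineralisation, dental follicle and periodontal ligament, Wnt, TGF-beta and BMP, FGF and Notch signalling, immediate early and AP-1, YAP/TEAD, contractile and matrix, primary cilium, dental epithelium, endothelium, blood and immune cells, neurons and glia, liver, ribosomal proteins, replication-dependent histones, respiratory chain, proteasome, Hox and chemosensory receptors. The last 6 were filled by patterns of gene symbols and the others by named genes. Named genes were all members with a boundary peak in the Hedgehog, imprinted and SWI/SNF lists, and peaks within 10 kb of Plagl1, Gli1, Ptch1, Arid1a and Arid1b with or without such a peak. The rule also took the 10 strongest peaks, the 10 strongest peaks with a boundary gene, and up to 4 members of every other list that was called or had at least 5 boundary peaks. Members named as lacking a boundary peak, members of the lists with under 5 boundary peaks that were not called, the fifth member of the odontoblast list, the histone members H3c8 and H4c14, the proteasome list members Psmc3ip and Psme3ip1, and genes named for peaks away from their boundaries, other than those of the rule, were chosen after their values were seen. A few genes that the rule takes are not reported here.

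Alternatives covered stricter q-values, a fold of at least 5, windows of 500 bp and 5 kb, peaks within 10 kb of the gene body matched on gene length, summits against any part of the peak, merging of intervals closer than 500 bp and boundaries of all genes. Matching on gene length or gene density at the boundary, summits shifted by 100 kb the restriction to peaks with background input and the proteasome list without Psmc3ip and Psme3ip1 were added after seeing the data. The procedures were tested on simulated data. Whole pileups were recovered for 100% of 972 simulated peaks and for 0% when pileups were not whole, and 100% of planted boundary positions were found. That last result checks the code only, since positions were planted within the same 1 kb that was searched. Of 100 simulated lists of 25 genes without a change 3% were called, and of 100 such lists in which the share of genes with a peak was raised from 20% to 50%, 80% were called. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.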

Results

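The series concerns Arid1a, Plagl1 and Hedgehog signalling in the cell cycle arrest that goes with differentiation of tooth root progenitors, per its title. The data described here are a chromatin immunoprecipitation with sequencing (ChIP-seq) of Arid1b, the paralogue of Arid1a and the other large ARID subunit of the BAF class of SWI/SNF chromatin remodelling complexes. The title and the design text name Arid1a and mice with a conditional Arid1a allele, whereas the sample labels name an Arid1b antibody and wild-type cells, and the target is given here as the sample labels state it. Arid1b was precipitated from primary dental mesenchyme cells of wild-type C57BL/6 mice. The cells came from the apical part of first mandibular molars at postnatal day 3.5 to 7.5 and were grown in medium with 10% serum. There were 2 libraries, 1 of the Arid1b ChIP and 1 of input chromatin without antibody, and the deposited list holds the peaks of the ChIP over the input. With 1 library per group there is no replicate check, and every value below describes these 2 libraries and not a difference between conditions. No library of Arid1a or of cells lacking it was analysed here, so the comparison addresses where Arid1b signal lay in wild-type cells.

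The list held 8318 peaks of Arid1b signal over input (6606 once intervals closer than 500 bp were merged). Nearly all of the 8318 were on autosomes. The 19 autosomes held 8273 peaks, chromosome X held 45 and chromosome Y held 0. Relative to the number of protein-coding genes, X held 4.66 peaks per 100 genes (exact Poisson 95% interval 3.40 to 6.23), whereas the autosomes ranged from 26.9 on chromosome 7 to 48.5 on chromosome 18. The peaks were narrow, with a median width of 307 bp (quartiles 237 and 452 bp), and together covered 3.48 Mb. The authors' fold enrichment at the summit had a median of 3.72 (quartiles 3.30 and 4.32) and ranged from 1.37 to 17.1, and their -log10 q ranged from 2.27 to 136 with a median of 8.47.

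**Figure D1:**
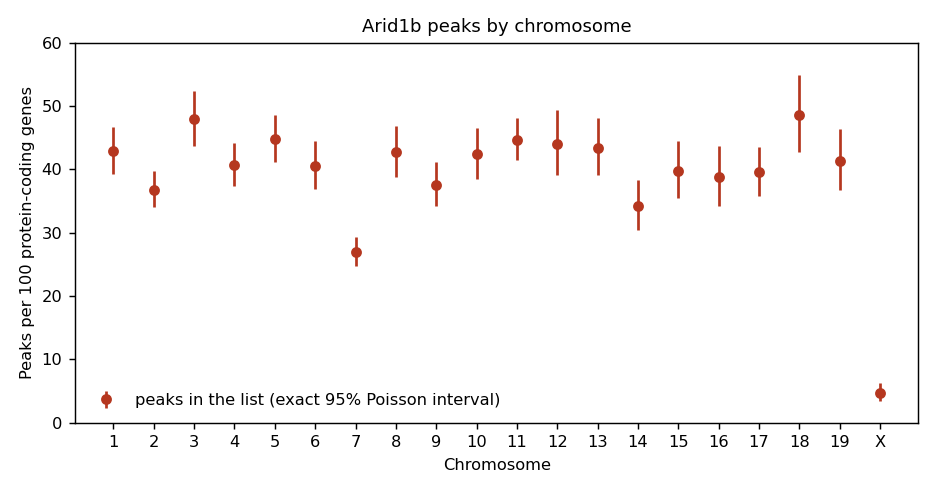
Arid1b peaks per 100 protein-coding genes (y axis) on each chromosome (x axis), where points are the counts in the peak list and bars their exact 95% Poisson intervals. Chromosome X lies at 4.66 and the 19 autosomes lie between 26.9 and 48.5.

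The depth behind single peaks was modest. The pileup at the summit, recovered from each fold and p-value, had a median of 38 fragments (quartiles 34 and 44), against a genome background level of 8.68. A pileup of 38 at that background gave a fold of 4.03 with an exact Poisson 95% interval of 2.88 to 5.49. For 7110 peaks (85.5%) the interval of the fold included the median fold of all peaks, so most peaks could not be told apart from the median at this depth. These intervals cover counting error only, and fragments are not necessarily independent molecules.

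Arid1b peaks concentrated at the ends of protein-coding genes. Of the 8318 summits, 4977 (59.8%, exact binomial 95% interval 58.8 to 60.9) lay within 1 kb of an annotated gene boundary, 18.6 times the 3.22% of 1000 random placements on the same chromosomes (central 95% 2.85 to 3.63). Against the same summits shifted by 100 kb to either side, of which 6.68% lay at a boundary, the ratio was 8.96. A further 2262 summits (27.2%, 26.2 to 28.2) lay inside a gene more than 1 kb from its ends, against 39.0% of random positions. The remaining 1079 (13.0%, 12.3 to 13.7) lay outside genes, against 57.7%. Of 21887 protein-coding genes, 4857 (22.2%) had part of a peak within 1 kb of a boundary and 6943 (31.7%) had one in the gene or within 10 kb of it. Start and end of a gene were not distinguished, because strand was not used here. Only the outer ends of each gene were used, so a peak at a start site inside a gene could count as interior. The share depended on the window, at 46.1% within 500 bp and 80.4% within 5 kb.

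**Figure D2:**
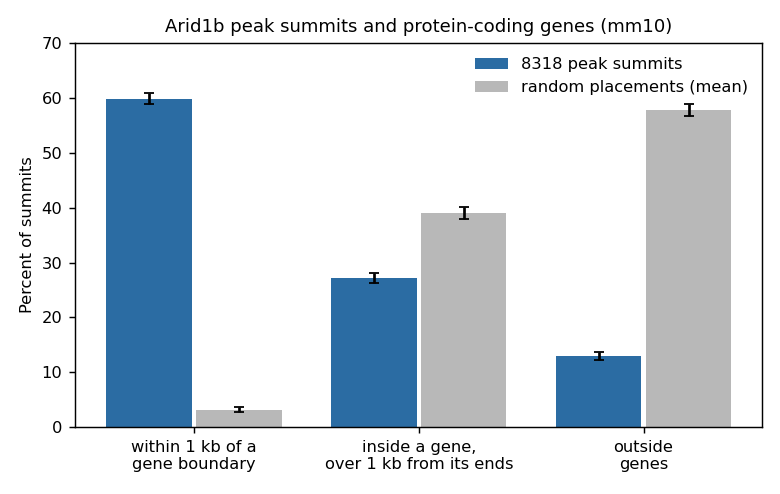
Percent of Arid1b peak summits (blue) and of random placements (grey, mean of 1000) in 3 classes of position relative to protein-coding genes, with exact binomial 95% intervals on the blue bars and the central 95% of placements on the grey bars. Summits within 1 kb of a gene boundary make up 59.8% of the peaks and 3.22% of the placements.

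Boundary peaks were slightly stronger than the other 3341 peaks. Their median fold was 3.82 against 3.61, a difference of 0.207 with a 95% bootstrap interval over peaks of 0.145 to 0.207. The upper end of the interval equals the estimate. The bootstrap describes the peaks of this list and not replicates.

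The strongest peak lay inside Sp2, a gene for a zinc-finger transcription factor of the Sp family, at chr11:96977034-96978125 (mm10), with a fold of 17.1 (14.6 to 19.9). It was followed by a peak at the boundary of Rnf44 (13.2) and by the widest peak of the list, 8992 bp on chromosome 6, whose summit lay 3166 bp from Igf2bp3 (12.6). The next were at the boundaries of Bcl6 (12.5), Nlk (11.8), Ppm1l (11.7), Atp5b (11.3) and Flcn (11.2). A peak 5840 bp from Srbd1 reached 10.9, and the peak at Osbp, at chr19:11965222-11965902, reached 10.8 (8.88 to 13.1). Of these 10 peaks, 7 had a protein-coding boundary within 1 kb, and the next boundary peaks by fold were at Fbxl14 (10.5), Cdkl3 (10.5) and the neighbours Mroh8 and Rpn2 (10.3). None of the 10 widest peaks had its summit within 1 kb of a protein-coding boundary.

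Hedgehog signalling genes carried Arid1b peaks at about the frequency of other genes. Of 21 members, 6 had a boundary peak: Cdon, a coreceptor for Hedgehog ligands, at 6.82 (5.28 to 8.66), Smo, the signal transducer of the pathway, at 4.40 (3.21 to 5.90), Spop at 4.13 (2.97 to 5.61), Sufu at 3.61 (2.53 to 5.01), Gas1 at 3.45 (2.42 to 4.78) and the transcription factor gene Gli3 at 3.18 (2.31 to 4.29). Ptch1, the Hedgehog receptor gene at chr13:63508328-63573460, had no boundary peak and 5 interior peaks, the strongest at chr13:63563154-63563558 with a fold of 5.23 (3.97 to 6.76) and the weakest with 2.98. Whether these interior peaks lie at a start site inside Ptch1 was not tested. Gli1, at chr10:127329882-127341579, had no peak within 10 kb, and the nearest lay 38745 bp away. Gli2 had 2 interior peaks, and in all 11 of the 21 members had a peak in the gene or within 10 kb.

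Among 10000 random lists of 21 protein-coding genes the mean was 4.68 genes with a boundary peak, and the Hedgehog list did not differ (two-sided share of random lists 0.637, Benjamini-Hochberg adjusted over 27 lists 0.717). The exact binomial 95% interval of its 28.6% runs from 11.3 to 52.2%, so a moderate excess or deficit was not detectable with a list of this size.

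Plagl1 itself, a zinc-finger transcription factor gene at chr10:13090832-13131694, had no Arid1b peak in the gene or within 10 kb, and the nearest peak lay 221323 bp away. None of the 20 protein-coding members of the list of Plagl1 and imprinted growth genes had a boundary peak, Igf2, Cdkn1c, Dlk1, Grb10, Mest and Peg3 among them, against a mean of 4.41 in random lists (adjusted share 0.0262). Some members are neighbours, while random genes were drawn singly. On chromosome 6, for example, Sgce ends at position 4747204 and Peg10 starts at 4747306. The random range may therefore be too narrow for this list, and the call is uncertain. Peaks farther from the ends were present at 6 of the 20, namely Zdbf2 (highest fold 8.67), Gnas (4.65), Igf2r (4.54), Nnat (4.35), Igf2 (3.61) and Impact (2.92). The lower count was not called with a window of 5 kb (2 of 20 against 5.36, 0.212) or when peaks within 10 kb of the gene counted (6 of 20 against 7.18, 0.815). With 500 bp (random mean 3.98, 0.0503) and over peaks whose local input lay at background (2.16, 0.428) the count was still 0, the lowest possible, and the call was lost with the lower random mean.

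Genes for SWI/SNF subunits, the complexes that Arid1b belongs to, had boundary peaks far more often than random genes. Of 28 members, 17 had one, against a mean of 6.19 in random lists (adjusted share 0.000675, from a two-sided share of 0.0002, the smallest that 10000 lists can give). Arid1b had a peak at its own boundary, chr17:4993788-4994547, with a fold of 6.41 (4.96 to 8.15), and further peaks of 4.85 and 4.40 inside the gene. Arid1a had one at chr4:133756522-133757870 with 5.60 (4.25 to 7.26) and a stronger interior one of 6.40 (4.92 to 8.19). The highest boundary peak of the list, 7.23 at Ss18l1, also lies at the proteasome gene Psma7. The others were Actl6a (5.58), Smarcc2 (5.05), Arid2 (4.85), Bcl7a (4.54), Smarce1 (4.46), Smarcc1 (4.34), Brd7 (4.24), Smarcd1 (4.13), Pbrm1 (3.92), the ATPase gene Smarca4 (3.72), Bicral (3.72), Bicra (3.58), Bcl7b (3.30) and Smarcd2 (2.65). The summit of the Bicra peak lay more than 1 kb from the boundary that the peak reached. No boundary peak was listed at the other ATPase gene Smarca2, at the core subunit gene Smarcb1, or at Smarcd3, Actl6b, Dpf1, Dpf2, Dpf3, Bcl7c, Brd9, Phf10 and Ss18. Ss18 had an interior peak at chr18:14682374-14683298, 1496 bp from its boundary, with a fold of 9.12 (7.52 to 11.0), higher than the boundary peaks of the list.

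**Figure D3:**
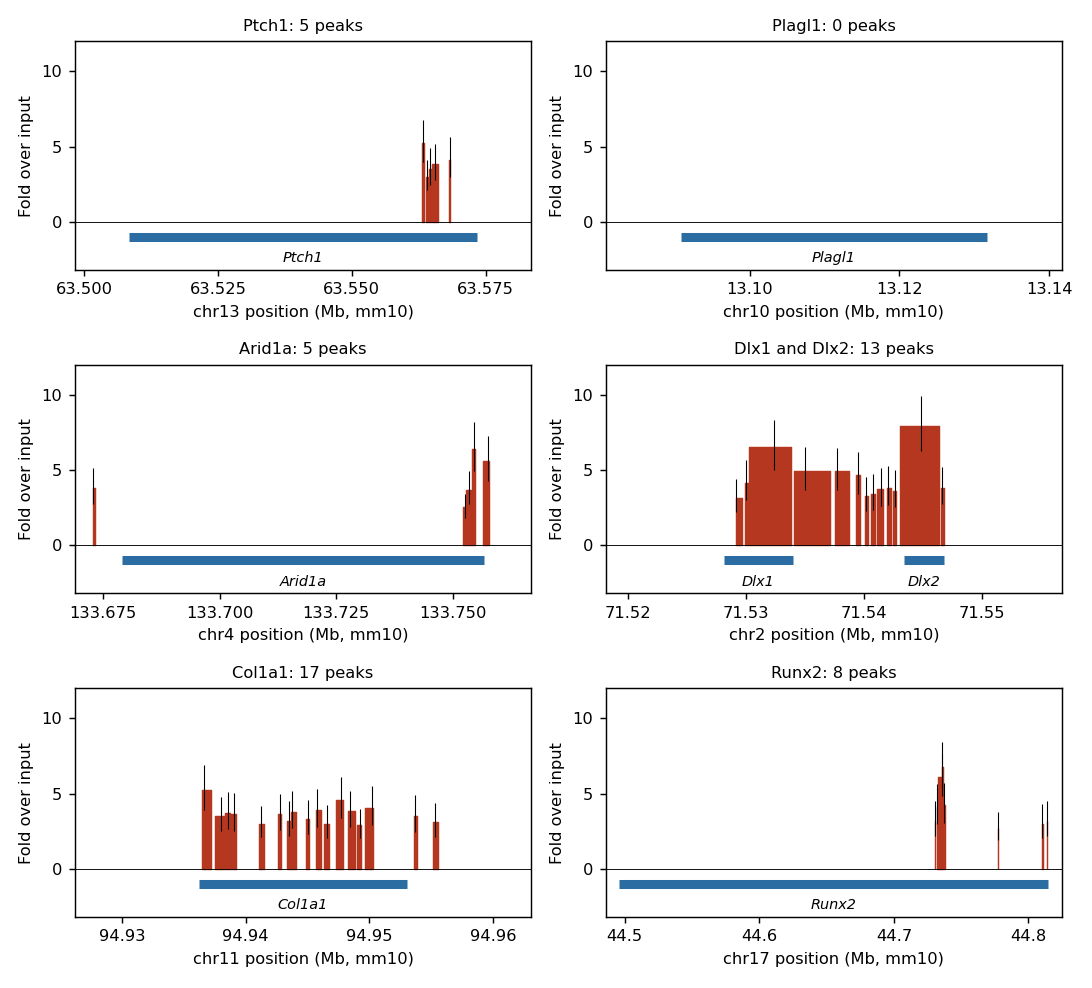
Arid1b peaks within 10 kb of 6 loci in mm10 coordinates, with genomic position in Mb on the x axis and the authors' fold over input on the y axis; red blocks span each peak at its summit fold, black lines are counting-only 95% intervals and blue bars are annotated genes. Plagl1 has 0 peaks, Ptch1 and Arid1a have 5 each, Runx2 has 8, the joint panel of Dlx1 and Dlx2 has 13 and Col1a1 has 17.

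Both sides of cell cycle control carried Arid1b peaks. Of 20 genes of cell cycle arrest, 16 had a boundary peak against a random mean of 4.44 (adjusted share 0.000675), the highest share of the 27 lists at 80.0%. The strongest were at Ccng2, an atypical cyclin (7.95, 6.29 to 9.93), the retinoblastoma relative Rbl1 (7.23, 5.65 to 9.12), the cyclin-dependent kinase inhibitor gene Cdkn1b (6.20, 4.74 to 7.96) and Btg1 (4.75, 3.49 to 6.32). The Cdkn1b peak reached within 1 kb of the boundary, but its summit at position 134926899 lay more than 1 kb beyond the high-coordinate end of the gene at 134925525. Whether that end is the start site was not tested. The 4 without a boundary peak were Cdkn1a, Cdkn1c, Cdkn2d and Rb1. Cdkn1a had a peak inside the gene, at chr17:29093880-29095189, with a fold of 5.41 (4.08 to 7.05). Cdkn1c, Cdkn2d and Rb1 had none in the gene or within 10 kb. Of 30 S and G2/M phase genes, 17 had a boundary peak against 6.66 (0.000675), led by the topoisomerase gene Top2a (7.85), the replication helicase genes Mcm4 (6.09) and Mcm7 (5.47), and the mitotic cyclin gene Ccnb2 (5.27). Whether the 2 lists differed from each other was not tested.

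Dental mesenchyme genes had boundary peaks more often than random genes, and the odontoblast and dental follicle lists were not called. Of 26 dental mesenchyme genes, 17 had a boundary peak against a random mean of 5.77 (adjusted share 0.000675), with the homeobox genes Dlx2 (7.95, 6.29 to 9.93), Lhx8 (7.02, 5.47 to 8.89) and Dlx1 (6.50, 5.01 to 8.31) among the highest. These wide peaks reached within 1 kb of the boundary, but their summits lay 1396, 1455 and 1617 bp from it. The odontoblast and mineralisation list had 5 of 20 against 4.39 (0.946), at Col1a1 (5.27), Sp7 (4.17), Col1a2 (3.61), Runx2 (3.20) and Sparc (2.41). The dentin and bone matrix genes Dspp, Dmp1, Bglap and Ibsp and the phosphatase gene Alpl had none. Runx2 had 8 peaks in all, and its strongest, inside the gene, reached 6.78. The summit of the Runx2 boundary peak lay 1141 bp from the boundary. The dental follicle and periodontal ligament list had 3 of 14 against 3.12 (adjusted share 1). Differences between these lists were not tested.

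Immediate early and AP-1, YAP/TEAD, TGF-beta and BMP signalling, and contractile and matrix genes were each called higher. Immediate early and AP-1 genes, which serum and growth factors induce, had boundary peaks at 21 of 28 members against 6.23 (0.000675), highest at Fos (8.16, 6.47 to 10.2), Fosl2 (7.33), Junb (5.89) and Ier3 (5.89). YAP/TEAD genes had 12 of 20 against 4.47 (0.0012), with Ccn2 (6.82), Lats2 (5.99), Tead1 (5.58) and Ajuba (5.47) highest. TGF-beta and BMP signalling had 15 of 30 against 6.66 (0.00687), led by the inhibitory Smad gene Smad7 (6.30), Tgif1 (5.03), Bmpr2 (4.96) and Smad3 (4.95). Contractile and matrix genes had 13 of 25 against 5.55 (0.00687), highest at Thbs1 and Cald1 (3.92), Tpm2 (3.84) and Tpm1 (3.78). This last call was lost with a window of 500 bp (9 against 5.01, 0.145) and over peaks whose local input lay at background (6 against 2.77, 0.238).

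Wnt, FGF and Notch signalling and the primary cilium were not called. FGF signalling had 10 of 24 against 5.34 (0.0816), with Spred1 (6.61), Etv5 (5.03), Spry2 (4.54) and Spred2 (4.19) highest. Wnt signalling had 8 of 30 against 6.66 (0.747), with Lrp6 (4.88), Fzd1 (4.34), Fzd7 (4.18) and Lgr4 (4.03) highest. Notch signalling had 6 of 19 against 4.25 (0.601), led by Hes1 (6.20), Maml3 (6.09), Maml1 (4.96) and Jag1 (3.43). Genes of the primary cilium, the organelle through which mammalian Hedgehog signals pass, had 7 of 25 against 5.53 (0.717), at Ift140 (5.68), Ift27 (5.16), Tulp3 (4.03) and Cep164 (3.94) among others.

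Ribosomal protein and Hox genes stood above random lists, and the call of the proteasome list depended on 2 of its members. Boundary peaks lay at 52 of 85 ribosomal protein genes against 18.9 (0.000675), highest at Rplp0 (6.71), Rpl7l1 (6.09), Rpl36al (5.68) and Rps26 (5.37). The proteasome list had 20 of 51 against 11.3 (0.0212), led by Psma7 (7.23), Psme2 (5.78), Psma2 (4.73) and Psme3 (4.54). This list was filled by gene symbol, and Psmc3ip and Psme3ip1, which do not encode proteasome subunits, are among the 20. Whether every other member encodes a subunit was not checked. Without these 2 genes it had 18 of 49 against 10.9 and was not called (0.0508), and it was also not called over the 3923 peaks whose local input lay at background, where it had 10 against 5.58 (0.235). Hox genes had 20 of 39 against 8.73 (0.000675), with Hoxd3 (6.30), Hoxd13 (6.01), Hoxb2 (5.87) and Hoxb9 (5.47) highest. They lie in clusters and neighbours can share a peak, as Hoxa5 and Hoxa6 did, while random genes were drawn singly. The random range may therefore be too narrow for Hox genes. Respiratory chain genes had 23 of 83 against 18.4 (0.370), although Atp5b (11.3, 9.25 to 13.6) and Ndufb1 (9.40, 7.69 to 11.4, a peak shared with the boundary of Cpsf2) were among the strong peaks, ahead of Uqcrh (6.71) and Atp5l (5.27).

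Chemosensory receptor genes were almost free of peaks, with a boundary peak at 1 of 1500, Olfr317 (3.56), against 333 in random lists (0.000675) and 105 in random lists matched on gene length (0.000675). Replication-dependent histone genes had 6 of 63 against 14.0 (0.0262), with 1 peak of 4.23 shared by H2ac21, H2ac20 and H2bc21 1 of 3.82 shared by H2ac10 and H3c8, and 1 of 3.03 at H4c14. Histone genes are short, and against random genes of like length the mean was 2.79 and the list was not called (0.165). Such random lists can include the nearly peak-free chemosensory receptors, so losing the call does not show that shortness lowered the count. Within 10 kb of the gene and matched on length, 11 histone genes had a peak against 4.81, which was called in the opposite direction (0.0233). Neighbouring histone genes can share a peak while random genes were drawn singly, so the random range may be too narrow for this list. The histone list was also not called with -log10 q of at least 5 (6 against 13.0, 0.0577) or with local input at background (5 against 6.95, 0.729).

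Of 5 lists of markers of cell types other than mesenchyme, only blood and immune cells were called lower, and the others were not called. Blood and immune cell genes had 0 of 18 against 4.01 (0.0403), a call that was lost in 6 of 9 alternatives (adjusted share up to 0.428). In 4 of these the count was still 0, against random means of 3.72 with -log10 q of at least 5, 3.63 with 500 bp, 3.62 matched on gene length and 1.99 with local input at background. Liver genes had 0 of 16 against 3.54 (0.0638) and were called lower with a window of 5 kb (0.0249) and for peaks within 10 kb of the gene (0.00765). Endothelial genes had 1 of 15, at Flt1, against 3.30 (0.365), and genes of neurons and glia had 1 of 18, at Neurod2 (3.58), against 3.96 (0.204). Dental epithelium had 3 of 21 against 4.67 (0.695), among them Sox2 (6.51, 5.01 to 8.31) and the enamel matrix gene Ambn (6.19, 4.90 to 7.73). Peaks do not name a cell type, and these counts only place the peaks at genes.

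**Figure D4:**
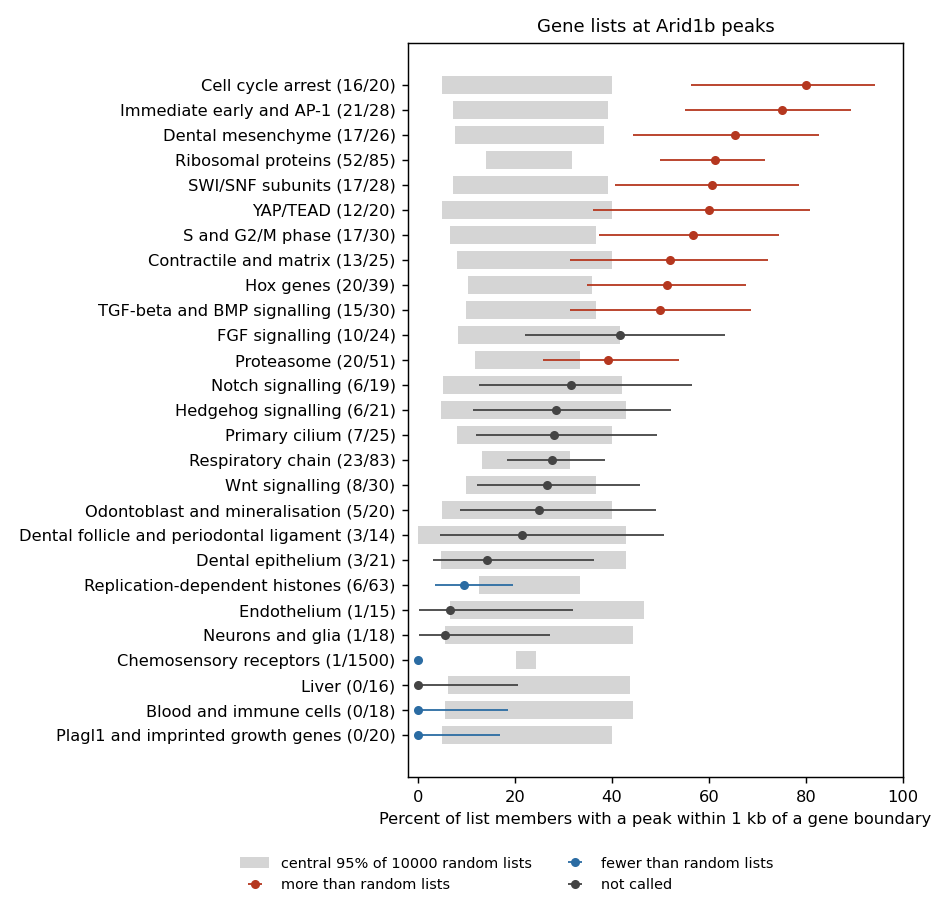
Percent of the members of 27 gene lists with an Arid1b peak within 1 kb of a gene boundary (x axis; points with exact binomial 95% intervals, members with a peak over members in the label), beside the central 95% of 10000 random lists (grey). Red points mark the 11 lists above random lists, blue the 4 below and dark grey the 12 not called.

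Across all lists, 11 were called higher, 4 lower and 12 not called. Of the 297 list members with a boundary peak, 65 (21.9%) shared their strongest one with the boundary of another protein-coding gene. Random lists were not matched on promoter GC content, so the calls compare each list with protein-coding genes at large. The shares describe this library pair and are not p-values across replicates.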

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

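Boundary, list and Hedgehog results were recomputed under the alternatives, of which the restriction to peaks with local input at background, the shift of summits, and the matching of boundary peaks on gene length or density were chosen after seeing the data. The Hedgehog list stayed uncalled under all 9 alternatives (3 to 11 genes, adjusted share 0.325 to 1). The excess in fold at boundaries stayed above 0 in all those run (0.144 to 0.310 in fold, 1.15 on -log10 q). Between 9 and 12 lists were called higher. Of the 11 called higher, 9 kept the call under all 9 alternatives, the contractile list under 7 and the proteasome under 8. Without Psmc3ip and Psme3ip1, left out after seeing the data, the proteasome list was not called (adjusted share 0.0508) and the other calls were the same, 10 higher and 4 lower. Of the 4 called lower, only the chemosensory list kept it under all 9, the imprinted list and the histones under 5 and the blood list under 3.

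The number of peaks was 848 with a fold of at least 5 and 3923 with local input at background, since both settings remove peaks. The boundary share was 61.1% with -log10 q of at least 5, 64.7% with a fold of at least 5, 46.1% with a window of 500 bp, 80.4% with 5 kb, 63.4% for any part of the peak, 65.7% with boundaries of all annotated genes, 62.5% after merging close intervals and 56.6% with local input at background. Narrower and wider windows and more boundaries change it by construction, and otherwise the cause was not tested. Shifting the summits by 100 kb raised the share expected by chance to 6.68% (6.35 and 7.01 for the 2 sides) and lowered the ratio of the boundary share to it from 18.6 to 8.96. Lists called lower numbered 2 with -log10 q of at least 5, 2 with a window of 500 bp, 2 with peaks within 10 kb of the gene body matched on length, 2 with boundary peaks matched on length and 1 with local input at background. For the histones matched on length the random mean fell from 14.0 to 2.79 genes, which ended the call. Where the imprinted list lost its call with 500 bp or local input at background, and the blood list with -log10 q of at least 5, 500 bp, matching on length or local input at background, the count stayed at 0 and the random mean was lower. For the other lists and settings the cause was not tested. The filter on repeats, matching on promoter GC content and all motif alternatives were not run. Depth limits the ranking of peaks, since the fold intervals of 85.5% of peaks include the median fold.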

Other observations

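The runs, families, gene types and low-fold peaks described first, the matching of families on gene length, the tests on gene ends and on chromosome X, and the transcribed list without members of other lists, were chosen after the results were seen. Peaks no more than 12.5 kb apart formed 5427 runs, of which 3905 held a single peak and 177 held at least 5. The longest run by number held 30 peaks over 76.6 kb of the Hoxa cluster, chr6:52191989-52268548. It was followed by Col1a1 with 17, the non-muscle myosin gene Myh9 with 15, and 13 each at Dlx1 with Dlx2 and at Dlx5 with Dlx6. Runs of 12 lay at Evx2 with Hoxd13, at Junb and at Irf2bp2, and runs of 10 at the long noncoding RNA genes Malat1 and Neat1. The Hox clusters differed in their counts: a boundary peak lay at 9 of 11 Hoxa, 6 of 10 Hoxb, 4 of 9 Hoxd and 1 of 9 Hoxc genes, differences that were not tested.

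Among 186 gene families defined by the stem of the symbol, with at least 12 genes each, 15 had more boundary peaks than random lists and 21 had fewer after adjustment over the families. Sorting nexins (Snx) had 18 of 30, BTB zinc-finger genes (Zbtb) 22 of 41, Rab GTPases 31 of 69, Klf factors 10 of 17 and proteasome genes with the stem Psmd 9 of 14. Keratins (Krt) had 0 of 53, keratin-associated proteins (Krtap) 0 of 56 and cytochrome P450 genes (Cyp) 4 of 99. Matched on gene length, 13 of the 15 and 12 of the 21 were still called. The named families were among them except Krtap, for which the random mean was 2.13 (adjusted share 0.398), and 4 further families were called lower. As for the histones, random genes matched on length can include the nearly peak-free chemosensory receptors. Losing the Krtap call therefore does not show that shortness lowered its count. Members of a family can be neighbours, while random genes were drawn singly, so the random ranges of families may be too narrow. By gene type, boundary peaks lay at 7.27% of long noncoding RNA genes, 5.70% of microRNA genes, 3.68% of tRNA genes (15 of 408) and 0.442% of pseudogenes. The 10 peaks with a fold below 2 had pileups of 81 to 368 over expected levels of 40.8 to 268. They lay on chromosome 2 (2 peaks between positions 98662413 and 98667152), at and within Sfi1 on chromosome 11, and on chromosome 1.

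Peaks lay at gene boundaries, and strand was not used to tell start from end. If peaks fell at both ends of a gene with equal chance and independently, 280 of the 16853 protein-coding genes over 5 kb would have had a peak at each end. There were 114, a ratio of 0.407, although the low-coordinate end (2193 genes) and the high-coordinate end (2154) were hit about equally often. The test argues against independent placement at the ends. A hypothesis consistent with this is that most peaks mark a single functional end such as the start site, which was not tested.

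Chromosome X had few peaks, and fewer genes do not account for it, since its 4.66 peaks per 100 genes lay below every autosome. Lower signal under a fixed calling threshold may account for part: thinning each autosomal pileup to 50% left 21.6% of autosomal peaks, and predicted 83.6 peaks for X against 45 (32.8 to 60.2). The bound first written, that the upper limit for X lie below the lowest thinned autosome, was met narrowly, 6.23 against 6.28 on chromosome 7. The counting limit of that autosome reaches 5.24 and the thinning is itself a simulation, so this explanation cannot be told apart, and the demand that the gap exceed counting error was added after the result was seen. The sex of the animals and mappability were not tested.

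Runs of peaks inside transcribed genes such as Col1a1 and Myh9 raised the hypothesis that signal follows strong transcription. A list of 40 genes strongly transcribed in fibroblasts was written from general knowledge before their interior peaks were counted, leaving out genes where the pattern had been noticed, though boundary peaks of some members, and for the gene lists the share of members with a peak in or near the gene, had been seen. The 31 members with a boundary peak held 38 interior summits, Cald1 (5) and Lmna (4) the most, against a mean of 7.95 (central 95% 1 to 19) in random lists of genes with a boundary peak matched on length, the 99.99th percentile, and 1 of 10000 random lists held as many. The 20 members on none of the 27 gene lists held 23 against 4.39 (0 to 12), the 99.93rd percentile. Start sites inside a gene were not annotated, so interior summits at such sites were counted too. The result is consistent with the hypothesis, and it does not separate Arid1b binding in open transcribed chromatin from nonspecific recovery of such chromatin, which remains open without an unrelated antibody.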
